A study of Mus musculus with 5 samples.

How the data were processed

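RNA of D4M.3A cells, a melanoma line from a C57BL/6 mouse, was sequenced in 5 libraries: 2 from cells with the pBABE vector, which the series text names as the reference control, and 3 from cells with caMNK, constitutively active MNK1. Per the labels' protocols, total RNA was prepared with the RNeasy Plus Mini Kit and made into libraries with Illumina's TruSeq Stranded Total RNA kit. Groups and replicate numbers were taken from the sample titles. The series text calls the libraries biological replicates of each cell line, without saying how the cultures were kept apart. The p-values here therefore measure the spread between these libraries. Group and cell line are the same, so another difference between the lines cannot be told apart from an effect of the kinase.

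The deposited files are tables of raw read counts per gene, 1 per library, with 46959 gene symbols and a length for each gene. Per the submitters' processing notes, Trimmomatic 0.32, FastQC 0.11.2, STAR 2.5.3, SAMtools 0.1.19, featureCounts 1.5.3 and DESeq2 were used with the mouse build mm10. The annotation release and the counting options are not given in the sources used here. What the authors counted was checked from the deposited values against GENCODE release M21, which is on the same build. Of 44118 genes with an entry of the same symbol, 37335 had a deposited length exactly equal to the genomic span of the gene, introns included. Among 27786 multi-exon genes, 21688 lengths equalled the span and 0 equalled the summed exons. Reads in a gene nested inside another were counted for both: of 353 nested protein-coding genes of 1000 or more summed counts on the strand of the outer gene, 352 had an outer gene with as many counts or more, and on the opposite strand this held for 153 of 156. For example, B2m had 53707 counts in pBABE replicate 1 and Patl2, which spans it on the opposite strand, had 54794. The counts therefore cover whole gene bodies, carry no strand information between overlapping genes and include intronic reads. A read in an overlap appears in the counts of both genes, and the library totals below include such reads more than once. Genes for which an overlapping gene has counts of 10% or more of their own are named with that gene in the text. This mark goes by the total counts of the overlapping gene, whatever the length of the overlap, which is 7 bp for mt-Nd4. The reads in common were not counted and can be few.

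Total counts per library were 42730166 and 32963884 in pBABE and 27827199, 48794336 and 36392842 in caMNK. Every library listed the same gene symbols. No pair of libraries was alike within sampling noise: the chi-square per degree of freedom of their counts was lowest for the pBABE pair, at 6.14, and 8.82 for caMNK replicates 1 and 3. It was 22.2 for caMNK replicates 1 and 2 and 49.4 for caMNK replicates 2 and 3, against 30.9 to 58.8 for pairs of a pBABE and a caMNK library.

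The comparison of caMNK with pBABE used edgeR 4.0.16 in R 4.3.3 on the deposited counts: filterByExpr by group, TMM scaling and the quasi-likelihood F test with robust estimation, on all 5 libraries with group as the only term. Adjusted p-values are Benjamini-Hochberg values over the 17026 genes that passed the filter, with a threshold of 0.05. Log2 fold changes are caMNK over pBABE, and each standard error (SE) is the size of the log2 fold change divided by the square root of F. CPM values are those of edgeR's cpm function on the TMM-scaled library totals and are given as mean ± SD over 2 pBABE and 3 caMNK libraries. A gene is called separated when every caMNK library lies on the same side of both pBABE libraries.

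Of 30 gene lists fixed before the data were examined, 21 cover biology, 4 cover RNA classes that vary with RNA quality or library preparation, and 5 hold markers of other cell types. The 28 lists with 5 or more tested members were tested with camera of limma 3.58.1 at the preset inter-gene correlation of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists. The same test with an estimated correlation and the rotation test fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the few libraries rather than from the genes. A call lost there therefore does not show that list members vary together. Members are also counted past the threshold over all genes tested and adjusted over the list alone.

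The genes named were set by a rule fixed before the data were examined. It takes Mknk1, Mknk2 and Eif4e; the 12 largest rises and the 12 largest falls among separated genes past the threshold with a mean log2 CPM of 3 or more, passing over symbols of predicted genes, clones and pseudogenes; the 4 members of each biology list with the lowest p; and the 3 most abundant members of each other list. It names 125 genes. The passing over went by symbol, so Mmp1a, which GENCODE gives as a polymorphic pseudogene, was kept. A further 25 genes are named outside the rule, chosen after their values were seen, and the text says so where they appear.

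The edgeR and camera steps were tested on simulated counts with the means and library sizes of this comparison, 16800 genes tested and 200 changed by known folds. The test recovered 50.7% of genes changed by 1.5-fold, 81.8% of those changed by 2-fold and 97% of those changed by 4-fold, and 4.24% of its calls were unchanged genes. The shifted list was called and 0 of 25 unshifted lists were. The simulated genes were drawn independently at the trended dispersion, with no library set apart from its group. The simulation therefore cannot show how camera at the preset correlation does where list members vary together. In the data the estimated correlation reached 0.788, for the interferon-stimulated genes.

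Alternatives fixed before the data were examined were DESeq2 size factors, total-count scaling and TMM without the 50 most abundant genes; no filter on low counts and a stricter filter (10 counts in every library of a group and a mean log2 CPM of 1); DESeq2 1.42.0 and limma-voom; the replicate number as a block; and leaving out each library. Adjusted p-values of the fits without a filter and with the block are not on the scale of the main fit, as given below for Mknk1. Leaving out genes that share reads with an overlapping gene, and the counts of list members without caMNK replicate 2, were added after the data were seen. The genes left out are those marked by the same 10% rule and those without a matching GENCODE entry. Genes with few reads in common can therefore be among them. The tests of explanations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with percentile intervals at 95% from 2000 bootstrap resamples of genes. These intervals do not measure the spread between libraries. Gene positions are those of GENCODE release M21 on mm10, 1-based. No deposited count column was left unused.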

Results

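MNK1, encoded by Mknk1, is a kinase that phosphorylates the cap-binding translation factor eIF4E and is itself activated by ERK and p38. D4M.3A is a mouse melanoma line that carries mutant Braf. The series compared these cells carrying the empty retroviral vector pBABE (n = 2 libraries, the reference) with cells carrying a constitutively active MNK1, called caMNK (n = 3). Total RNA was sequenced, and read counts per gene body were compared. The libraries held between 27827199 and 48794336 counts, and between 22686 and 24034 genes had at least 1 count. The first principal component of log2 CPM held 58.1% of the variance and parted the groups. The second held 21.3% and parted caMNK replicate 2 (−31.8) from caMNK replicate 3 (21.7).

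Mknk1 was higher in every caMNK library. It measured 15.2 and 16.7 CPM in the pBABE libraries and 167, 155 and 168 CPM in the caMNK libraries, a 10.2-fold rise (log2 fold change 3.36, SE 0.104, edgeR adjusted p = 4.81e-06). The gene lies on chromosome 4 from 115839198 to 115879250 on the plus strand. The counts are of the mouse gene, and the labels do not give the species or extent of the introduced cDNA, so reads from a cDNA of another species would be counted only in part. The related kinase Mknk2 measured 47.3 ± 1.60 and 53.5 ± 7.60 CPM in pBABE and caMNK (adjusted p = 0.416; log2 fold change 0.28, adjusted p = 0.0124, without caMNK replicate 2), and Eif4e 232 ± 0.779 and 246 ± 12.0 CPM (adjusted p = 0.567). Of the 19 members of the MNK and eIF4E pathway list, Mknk1 was the member past the threshold with all libraries, 3 rose and 1 fell when adjusted over the list alone, and 4 rose and 6 fell without caMNK replicate 2. Eif4ebp2, a translation repressor that binds eIF4E, had a log2 fold change of −0.40 (adjusted p = 0.0544), Eif4ebp3 0.45 (0.0598) and the helicase gene Eif4a2, which shares reads with Rfc4, 0.27 (0.0722). Without caMNK replicate 2 these 3 genes passed, with adjusted p-values of 0.000507, 0.0197 and 0.00907, and Eif4ebp2 passed by DESeq2 (0.0330) and without a filter on low counts (0.0105). Eif4ebp3 and Eif4a2 passed with total-count scaling (0.0433 and 0.0401). The list's median was −0.07 and its mean 0.13, or −0.052 over the 18 members other than the introduced Mknk1. The camera direction was down (adjusted p = 0.793) and the fry direction, with Mknk1 in the list, was up (adjusted p = 0.0141), so the signs differ.

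Of 17026 genes tested, 753 rose and 599 fell in caMNK, and 363 rose and 104 fell by at least 2-fold. All 1352 called genes were separated between the groups in every library. Separation held for 44.9% of all tested genes, where chance gives 20%. With total-count scaling, which shifted the median of all genes by 0.05, 999 genes rose and 465 fell, so that 68.2% of calls were rises against 55.7% with TMM. The 2-fold calls were mostly of low-abundance genes: 308 rose and 86 fell under a mean log2 CPM of 3, against 55 and 18 at 3 or more. In all, 353 genes rose and 429 fell at 3 or more. The counts depended on single libraries. Without pBABE replicate 1, 11 genes rose and 12 fell, and without pBABE replicate 2, 37 rose and 18 fell. Without caMNK replicate 1 the counts were 175 and 80, and without caMNK replicate 2 they were 2325 and 2617. Of the 108 named genes past the threshold, 18, 25 and 51 passed without pBABE replicate 1, pBABE replicate 2 and caMNK replicate 1, and each of the 108 kept its direction in those fits. For separated genes the direction in a fit without a library is all but fixed in advance, so the kept direction is no further support. With shared reads, 247 called genes overlapped another called gene of the same direction. Leaving out genes that share reads gave 402 rises and 282 falls among 9881 genes.

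Among genes with a mean log2 CPM of 3 or more that the naming rule takes, the largest rises after Mknk1 included genes of secreted proteases and a growth-response transcription factor. Mmp9, which encodes a gelatinase, rose from 2.52 ± 0.196 to 18.8 ± 6.40 CPM, 7.38-fold (log2 fold change 2.88, SE 0.315, adjusted p = 0.00465). The collagenase gene Mmp1a, annotated as a polymorphic pseudogene (chromosome 9, 7464141 to 7476869) rose 4.67-fold to 14.6 ± 1.96 CPM, and the stromelysin gene Mmp10 rose 3.08-fold to 46.6 ± 8.28 CPM. Egr1 (chromosome 18, 34859823 to 34864984), an immediate early transcription factor, rose from 23.1 ± 5.44 to 101 ± 13.9 CPM, 4.37-fold (log2 fold change 2.13, SE 0.174, adjusted p = 0.00170). The mineralization inhibitor Mgp rose 3.52-fold, the keratin gene Krt20 3.91-fold, the secreted chaperone gene Clu 3.28-fold, the cell adhesion gene Nrcam 3.42-fold and the exocrine peptide gene Esp15 3.93-fold. Dnm3os rose from 3.78 CPM to 15.1 CPM and Dnm3 3.40-fold. Dnm3os lies inside Dnm3 on the opposite strand, Dnm3 also shares reads with Gm38304, and these reads cannot be told apart. Adjusted p-values of the genes given by fold alone lay between 0.00121 and 0.00635. Of the 12 rises, 8 passed without pBABE replicate 1 and 11 without pBABE replicate 2.

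Among genes with a mean log2 CPM of 3 or more that the naming rule takes, the largest fall was that of Cth (chromosome 3, 157894248 to 157925077), the cystathionine gamma-lyase that makes cysteine, from 44.5 ± 0.600 to 9.75 ± 1.85 CPM, 4.52-fold lower (log2 fold change −2.18, SE 0.145, adjusted p = 0.000866). Further enzyme genes were among the falls. The mitochondrial folate enzyme gene Aldh1l2, which shares reads with D10Wsu102e, fell from 185 ± 18.4 to 75.1 ± 16.7 CPM, the proline synthesis gene Pycr1 from 19 ± 4.24 to 8.74 ± 0.668 CPM, the pyruvate dehydrogenase kinase gene Pdk1 from 50.3 ± 2.18 to 22.5 ± 1.70 CPM and the purine oxidase gene Xdh from 18.7 ± 0.3 to 7.31 ± 1.65 CPM. Their log2 fold changes were −1.30, −1.12, −1.16 and −1.35. Cd34, a surface sialomucin gene whose span shares reads with Gm16897, fell 2.85-fold, and the basement membrane collagen gene Col4a6 fell 2.67-fold. The endocytic adaptor gene Snap91 fell 2.93-fold, the natriuretic peptide receptor gene Npr3 2.15-fold, Adamtsl3 2.30-fold and the AP-1 gene Fosb 2.31-fold. Mir5114 fell 2.23-fold. It lies inside Scd2, the stearoyl-CoA desaturase gene, and shares the reads of this host, which had a log2 fold change of −0.68 and is named outside the rule. Adjusted p-values of these 11 genes lay between 0.000522 and 0.00985. Of the 12 falls, 7 passed without pBABE replicate 1 and 8 without pBABE replicate 2.

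**Figure D1:**
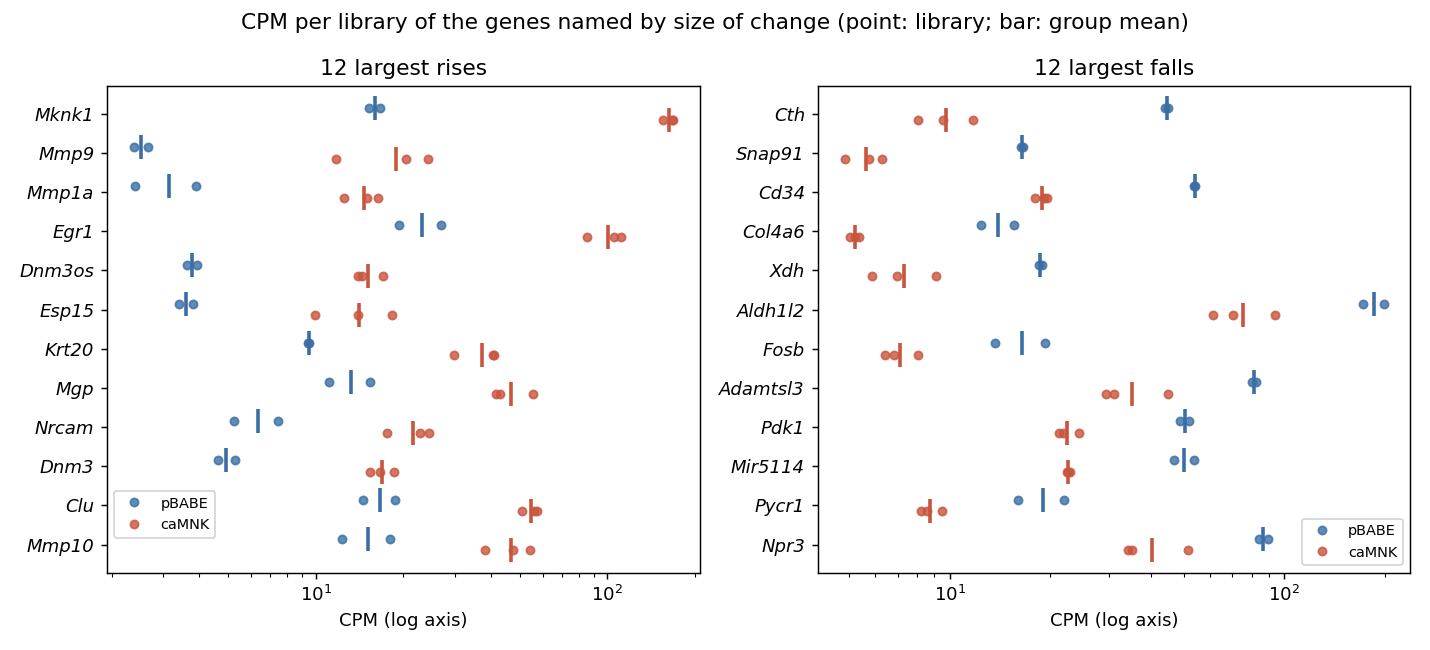
CPM on a log axis of the 12 largest rises and the 12 largest falls that the naming rule takes. The rule takes called, separated genes with a mean log2 CPM of 3 or more and passes over symbols of predicted genes, clones and pseudogenes. Each point is a library (2 pBABE, 3 caMNK) and each bar a group mean. Mknk1 lies near 15.9 CPM in pBABE and 163 CPM in caMNK. The points of the groups are apart for every gene shown, as the rule requires.

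The lists of amino acid supply, hypoxia and glycolysis, and cholesterol synthesis were called lower in caMNK. In the list of ATF4 targets, which supply amino acids and charge tRNAs, 24 of 37 members fell and 1 rose, and 30 fell and 1 rose when adjusted over the list alone (median log2 fold change −0.39, camera adjusted p = 1.79e-10; adjusted p = 0.454 with an estimated correlation). The amino acid transporter gene Slc7a5 fell from 285 ± 8.76 to 165 ± 16.8 CPM (log2 fold change −0.79, SE 0.101, adjusted p = 0.00635). Its whole span lies within the read-through gene Gm20388. The serine synthesis genes Psat1 and Phgdh had log2 fold changes of −0.71 and −0.66, both with an adjusted p of 0.00748. The member that rose, chosen after its values were seen and outside the naming rule, was Nupr1, a stress-induced chromatin protein gene (log2 fold change 0.63, adjusted p = 0.00900). In the hypoxia and glycolysis list, 15 of 34 members fell and 0 rose, and 18 fell when adjusted over the list alone (median −0.36, camera adjusted p = 3.73e-07; adjusted p = 0.454 with an estimated correlation). Beside Pdk1, they included the prolyl hydroxylase gene Egln3 (log2 fold change −0.69), the disulfide oxidase gene Ero1l (−0.90) and the lactate transporter gene Slc16a3 (−1.38, from 2.93 ± 0.202 to 1.13 ± 0.128 CPM). In the cholesterol synthesis list, 13 of 25 members fell and 0 rose, and 20 fell when adjusted over the list alone (median −0.41, camera adjusted p = 2.09e-08; adjusted p = 0.454 with an estimated correlation). Sqle and Nsdhl had log2 fold changes of −0.58 and −0.61, Lss, which shares reads with 4930483K19Rik, −0.61, and Srebf2, the transcription factor of the pathway, −0.52, with adjusted p-values between 0.0103 and 0.0131. Over the 95 members of the 3 lists, 53 passed with all libraries, 1 without pBABE replicate 1, 2 without pBABE replicate 2 and 13 without caMNK replicate 1. In the same comparison, 6 of 10 mitochondrial mRNAs and 6 of 11 nuclear non-coding RNAs rose.

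ERK signalling induces feedback inhibitors and immediate early transcription factors. Of 24 ERK output members, 7 rose and 0 fell, and 10 rose when adjusted over the list alone (median 0.10, camera adjusted p = 0.0241; adjusted p = 0.488 with an estimated correlation). Beside Egr1, the ERK phosphatase genes Dusp6 and Dusp5 rose from 99.8 ± 0.281 to 161 ± 2.40 CPM and from 38 ± 5.86 to 64.4 ± 8.37 CPM, and the feedback inhibitor gene Spry4 from 68.3 ± 4.82 to 108 ± 8.80 CPM. Their adjusted p-values lay between 0.00510 and 0.0164. Of 27 immediate early genes, 7 rose and 3 fell, and 13 rose and 4 fell when adjusted over the list alone (median 0.26, camera adjusted p = 0.0286; adjusted p = 0.454 with an estimated correlation). Fos (chromosome 12, 85473890 to 85477273) fell from 10.5 ± 0.555 to 2.42 ± 0.649 CPM, 4.42-fold lower (log2 fold change −2.15, SE 0.201, adjusted p = 0.00283). The falls were in Fos, Fosb and, outside the naming rule, Jund, which shares reads with Gm11175 (−0.54, adjusted p = 0.0333). Ier2 rose 1.70-fold (adjusted p = 0.0121). Without pBABE replicate 1 the calls of both lists were lost (adjusted p of 0.0931 and 0.0941), and that of the immediate early genes was lost without caMNK replicate 3 (0.0743) and without a filter on low counts (0.0632). Of the 49 members of both lists, 15 passed with all libraries, 3 without pBABE replicate 1, 2 without pBABE replicate 2, 4 without caMNK replicate 1 and 29 without caMNK replicate 2. In the same libraries, 6 of 10 mitochondrial mRNAs rose.

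Of 34 matrix protease and inhibitor genes, 8 rose and 2 fell, and 9 rose and 5 fell when adjusted over the list alone (median 0.13, camera adjusted p = 0.169, not called). Beside Mmp9 and Mmp10, Mmp3 rose from 35.9 ± 7.58 to 99.2 ± 14.2 CPM (log2 fold change 1.47, SE 0.162, adjusted p = 0.00470), and Plat, tissue plasminogen activator, from 23.5 ± 1.26 to 42.3 ± 2.11 CPM. The falls, outside the naming rule, were in the sheddase gene Adam9 (−0.46) and in Adam19 (−0.42), which shares reads with Gm16033 and whose call was lost with total-count scaling (adjusted p = 0.0515) and the stricter filter (0.0547). Of 46 extracellular matrix genes, 5 rose and 10 fell, and 7 rose and 18 fell when adjusted over the list alone (median −0.17, camera adjusted p = 0.0898, not called). Beside Mgp, the rises, outside the naming rule, were in Thbs1 (0.57), Thbs2 (0.72), the laminin gene Lama4 (0.50) and the fibrillar collagen gene Col1a2 (0.84). The latent TGF-beta binding gene Ltbp2 fell 1.53-fold, and the fibrillar collagen gene Col5a2 1.79-fold. The basement membrane collagen gene Col4a1, which overlaps its neighbour Col4a2 by 22 bp, fell 1.47-fold. Of 32 cytokine and chemokine genes, 8 rose and 4 fell, and 16 rose and 5 fell when adjusted over the list alone (median 0.33, camera adjusted p = 0.0292; adjusted p = 0.454 with an estimated correlation). The T cell attractant gene Ccl5 rose from 6.98 ± 0.579 to 14.5 ± 1.15 CPM (adjusted p = 0.00524), the cytokine gene Il11 from 16.7 ± 1.97 to 34.9 ± 7.40 CPM (0.0131) and Cx3cl1 from 60.4 ± 0.368 to 89.7 ± 7.59 CPM (0.0134). Cxcl14 fell from 1.60 ± 0.153 to 0.684 ± 0.0116 CPM (0.0165). Outside the naming rule, the macrophage growth factor gene Csf1 (−0.39), Vegfb (−0.46) and Mif (−0.41) fell. The call of Mif, at an adjusted p of 0.0498, was lost with total-count scaling (0.0587), limma-voom (0.0540), TMM without the 50 most abundant genes (0.0502), the stricter filter (0.0626) and without genes that share reads (0.0574). The cytokine list lost its call without pBABE replicate 2 (adjusted p = 0.0748), caMNK replicate 2 (0.0515) or caMNK replicate 3 (0.0535), with total-count scaling (0.0631) and without genes that share reads (0.16). Of 29 NF-kB targets, 5 rose and 0 fell, and 6 rose when adjusted over the list alone (median 0.13, camera adjusted p = 0.0898, not called; 0.0203 with the stricter filter and 0.0483 without caMNK replicate 2). Ptgs2, the inducible prostaglandin synthase gene, rose 1.59-fold, Ier3 1.51-fold (adjusted p = 0.0430; 0.0538 with the stricter filter) and the monocyte attractant gene Ccl2, which shares reads with Gm17268, 1.35-fold. Outside the naming rule, the iron-binding gene Lcn2 rose 2.04-fold (adjusted p = 0.0444; 0.0558 with the stricter filter, 0.0539 by limma-voom and 0.0507 without genes that share reads). Of the 135 members of the 4 lists, 40 passed with all libraries, 1 without pBABE replicate 1, 5 without pBABE replicate 2, 8 without caMNK replicate 1 and 80 without caMNK replicate 2. Of the mitochondrial mRNAs, 6 of 10 rose beside these genes, and of the nuclear non-coding RNAs 6 of 11.

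Markers of melanoma cell states moved in part. Of 32 genes of the invasive and undifferentiated state, 5 rose and 1 fell, and 9 rose and 4 fell when adjusted over the list alone (median 0.22, camera adjusted p = 0.0286; adjusted p = 0.454 with an estimated correlation). The transcription factor genes Sox9 and Snai1 rose from 22.3 ± 1.68 to 46.4 ± 3.62 CPM and from 5.46 ± 0.222 to 11.8 ± 0.903 CPM, and the activin subunit gene Inhba rose 1.72-fold. Outside the naming rule, the kinase gene Nuak1 rose 1.29-fold and the matrix gene Thbs1 1.49-fold. Wnt5a, a ligand of non-canonical Wnt signalling, fell 1.89-fold (adjusted p = 0.00941). The list lost its call without pBABE replicate 1 (adjusted p = 0.116), without a filter on low counts (0.0632) and without genes that share reads (0.0694). Of 14 neural crest-like genes, 4 rose and 0 fell, and 5 rose and 2 fell when adjusted over the list alone (median 0.26, camera adjusted p = 0.0898, not called; 0.00254 with the stricter filter and 0.00284 by fry). Slitrk6 rose from 1.74 ± 0.0835 to 7.83 ± 0.654 CPM (log2 fold change 2.18, SE 0.161, adjusted p = 0.00121). The transcription factor gene Tfap2b rose from 121 ± 2.15 to 200 ± 11.6 CPM, Tfap2a, which shares reads with Gm26688, 1.48-fold and Sox2, which lies inside Sox2ot and shares its reads, 1.53-fold. Of 26 pigment cell genes, 11 were abundant enough to test. None of them passed in the main edgeR comparison, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.169). Without caMNK replicate 2, 3 rose and 2 fell. Bace2 measured 0.457 ± 0.0325 and 1.0 ± 0.174 CPM (adjusted p = 0.0553), Hps4, which shares reads with Gm20636, had a log2 fold change of −0.40 (0.0589), Slc24a5, which shares reads with Myef2, 0.29 (0.238) and Cdk2 0.20 (0.240). Without caMNK replicate 2, Bace2 (0.00945), Hps4 (0.0155) and Cdk2 (0.0137) passed, and without a filter on low counts Bace2 (0.0144) and Hps4 (0.0375). Bace2 passed with total-count scaling (0.0479) and Hps4 without caMNK replicate 3 (0.0498). Of the 56 members of these lists, 10 passed with all libraries, 1 without pBABE replicate 1, 2 without pBABE replicate 2, 4 without caMNK replicate 1 and 30 without caMNK replicate 2. Of the nuclear non-coding RNAs, 6 of 11 rose in the same libraries.

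Interferon-stimulated genes were higher as a list, while antigen presentation genes were not called. Of 48 interferon-stimulated members, 6 rose and 0 fell, and 12 rose when adjusted over the list alone (median 0.36, camera adjusted p = 4.61e-06; adjusted p = 0.589 with an estimated correlation; fry adjusted p = 0.232). Oas1b and Mx2, interferon-induced genes annotated as polymorphic pseudogenes, rose from 8.07 ± 0.420 to 17.4 ± 0.213 CPM and from 12.9 ± 2.33 to 23.7 ± 5.92 CPM. Stat2, which transmits interferon signals, rose 1.70-fold and Oasl1 1.69-fold, with adjusted p-values between 0.00285 and 0.0381 for these 4 genes. Of 22 antigen presentation genes, 0 passed in the main edgeR comparison, also when adjusted over the list alone (median 0.013, camera adjusted p = 0.805). Without caMNK replicate 2, 2 fell. H2-Q7, a class I gene with close paralogs, had a log2 fold change of −0.66 (adjusted p = 0.165), the proteasome subunit gene Psmb10, which shares reads with Gm16156, 0.37 (0.177), Nlrc5 0.28 (0.181) and the chaperone gene Canx −0.20 (0.215). H2-Q7 passed without caMNK replicate 3 (0.0121) and without a filter on low counts (0.00213), Psmb10 without that filter (0.0354) and Canx without caMNK replicate 2 (0.00766). Of the 70 members of both lists, 6 passed with all libraries, 0 without pBABE replicate 1, 0 without pBABE replicate 2, 2 without caMNK replicate 1 and 13 without caMNK replicate 2. In the same libraries, 6 of 10 mitochondrial mRNAs rose.

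Among the remaining lists, G2 and M phase genes, ER stress chaperones, and YAP and TEAD targets were called lower. Of 38 G2 and M phase genes, the spindle checkpoint kinase gene Bub1b fell (168 ± 0.654 to 130 ± 2.65 CPM, adjusted p = 0.0284) and 0 rose, 0 passed when adjusted over the list alone, and 15 fell without caMNK replicate 2. The list's median was −0.13 (camera adjusted p = 0.0193; adjusted p = 0.597 with an estimated correlation; 0.198 without caMNK replicate 3, 0.0542 without genes that share reads and 0.237 by fry). Nek2, Cenpf and Plk1 had log2 fold changes of −0.26, −0.42 and −0.22 with adjusted p-values between 0.118 and 0.144, and passed without caMNK replicate 2 (0.0373, 0.00124 and 0.0471), as did Cenpf without a filter on low counts (0.00155). Of 24 ER stress chaperone genes, 4 fell and 0 rose, both over all genes and adjusted over the list alone (median −0.10, camera adjusted p = 0.0286; adjusted p = 0.510 with an estimated correlation). Herpud1 (−0.50), which shares reads with Gm15890, Atf6 (−0.51), Sel1l (−0.45) and Sdf2l1 (−0.44) fell, that of Sdf2l1 not with total-count scaling (adjusted p = 0.0612), the stricter filter (0.0559) or without genes that share reads (0.0525). The list lost its call without pBABE replicate 1 (0.0941) or caMNK replicate 1 (0.104), with the stricter filter (0.0580), without genes that share reads (0.0804) and by fry (0.0865). Of 22 YAP and TEAD targets, Ptpn14 (−0.56) and Crim1 (−0.47), which shares reads with Fez2, fell and Rbms3 rose (0.65), and 10 fell and 1 rose when adjusted over the list alone. Arhgef17 had a log2 fold change of −0.31 (adjusted p = 0.0553; 0.0445 by DESeq2, 0.0305 without a filter on low counts and 0.00423 without caMNK replicate 2). The list's median was −0.20 (camera adjusted p = 0.0328; adjusted p = 0.454 with an estimated correlation), and the call was lost in each of the 5 fits without a library, with adjusted p-values from 0.0504 to 0.0743, and with the stricter filter (0.0580). Of 23 p53 targets, the cell death gene Pmaip1 (0.94, adjusted p = 0.0247) and the kinase gene Plk3 (0.62, 0.0433; 0.0534 by limma-voom and 0.0532 with the stricter filter) rose and 0 fell, and 3 rose and 1 fell when adjusted over the list alone. The p53 list's median was −0.010, its mean was 0.095 and its camera direction was up (adjusted p = 0.627). Btg2 and Zmat3 had log2 fold changes of 0.65 (0.0549) and −0.32 (0.0667), and passed without caMNK replicate 2 (0.000139 and 0.00695) and without a filter on low counts (0.00111 and 0.0353). Btg2 also passed with total-count scaling (0.0458) and by DESeq2 (0.0119). Of 38 S phase genes and 35 lysosome genes, 0 passed with all libraries, over all genes or adjusted over the list alone (camera adjusted p = 0.793 for both). Without caMNK replicate 2, 2 S phase genes rose and 3 fell, and 8 lysosome genes rose and 3 fell. The S phase list's median was 0.0010 and its mean −0.0042, and the lysosome list's median was 0.0030 and its mean −0.00064. The S phase genes with the lowest p were Lig1 (−0.26), Pola1 (−0.39), Prim1 (0.23) and Mcm2 (−0.22). The lysosome genes were Npc2 (0.38), Ctsh (0.27), Asah1 (−0.19) and Ctsz (−0.32), which overlaps Nelfcd by 10 bp. Of these, Lig1 (0.00686), Pola1 (8.13e-05), Prim1 (0.0167), Npc2 (0.00283), Ctsh (0.00389) and Asah1 (0.0119) passed without caMNK replicate 2 and Ctsz without caMNK replicate 3 (0.0251). Pola1 (0.00443), Npc2 (0.00489) and Ctsz (0.0255) passed without a filter on low counts and Npc2 by DESeq2 (0.0426). Over the 199 members of these lists and the MNK list, 11 passed with all libraries, 1 without pBABE replicate 1, 1 without pBABE replicate 2, 1 without caMNK replicate 1 and 72 without caMNK replicate 2. Beside them, 6 of 10 mitochondrial mRNAs and 6 of 11 nuclear non-coding RNAs rose in this comparison.

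**Figure D2:**
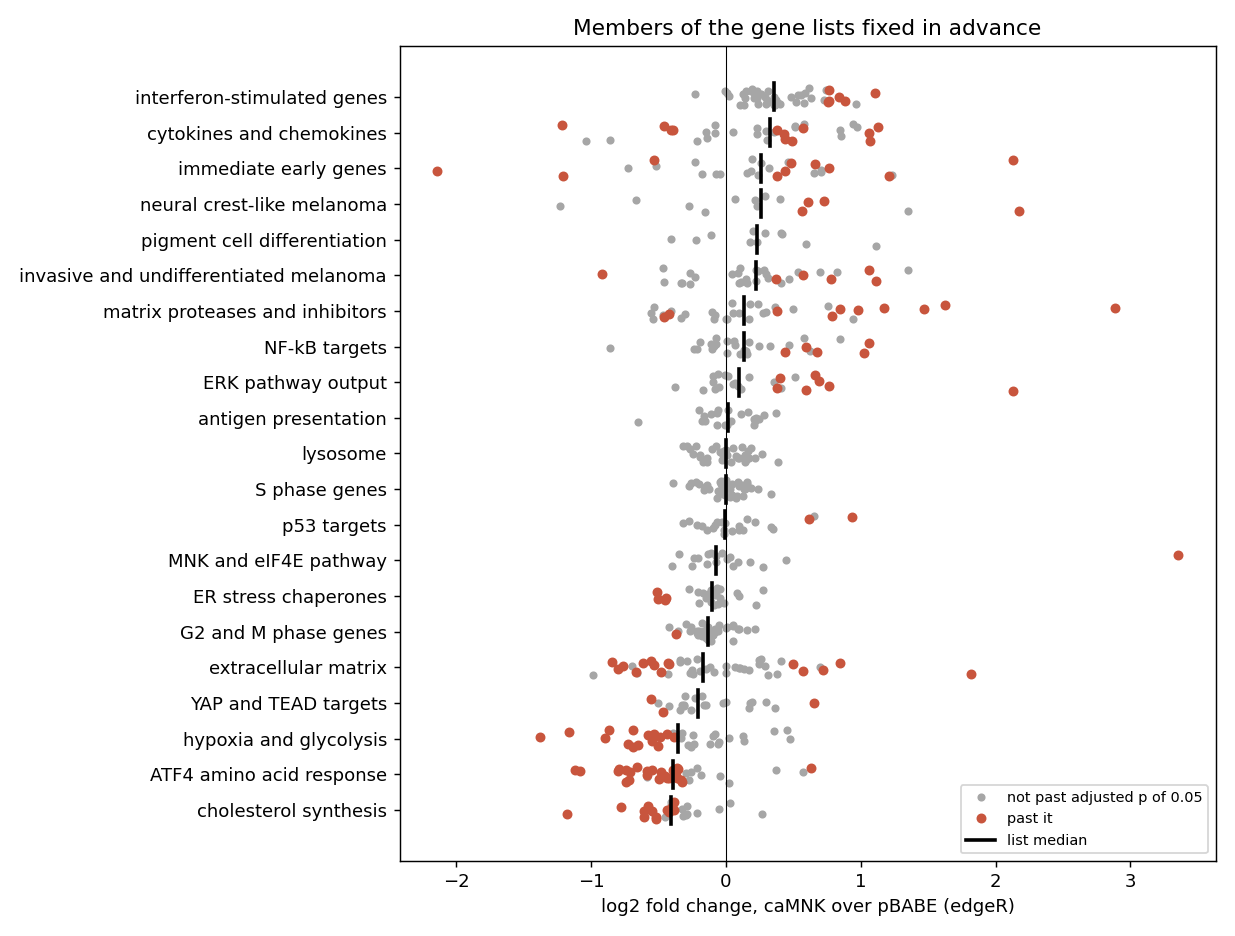
Log2 fold change (caMNK over pBABE, edgeR) of each tested member of the 21 biology lists; points past the adjusted p threshold of 0.05 are coloured and black bars mark list medians. The medians of the cholesterol, ATF4 and hypoxia lists lie lowest, at −0.41, −0.39 and −0.36, and that of the interferon-stimulated genes highest, at 0.36.

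Among RNA classes that vary with RNA quality or library preparation, mitochondrial mRNAs and nuclear non-coding RNAs had members past the threshold. Genes of the mitochondrial genome took 1.33% and 1.48% of counts in pBABE and 2.13%, 2.37% and 2.08% in caMNK. Of 10 mitochondrial mRNAs tested, 6 rose and 0 fell, and 9 rose when adjusted over the list alone (median 0.67, camera adjusted p = 0.000334; adjusted p = 0.454 with an estimated correlation). mt-Co1, mt-Cytb and mt-Nd4, which overlaps mt-Nd4l, had log2 fold changes of 0.49, 0.70 and 0.74. Of 11 nuclear non-coding RNAs, 6 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone (median 1.06, camera adjusted p = 0.00227; adjusted p = 0.454 with an estimated correlation; 0.146 without genes that share reads). Malat1, which shares reads with Gm37376, rose from 169 ± 0.296 to 392 ± 119 CPM and Neat1 from 88.0 ± 3.85 to 223 ± 44.1 CPM. Gas5, a snoRNA host, rose 1.27-fold. The fall, outside the naming rule, was that of Rpph1, the RNA of RNase P (−1.29, adjusted p = 0.0236). Of 19 histone genes, 0 passed with all libraries, also when adjusted over the list alone, and 6 rose and 2 fell without caMNK replicate 2, with a median of 0.36 (camera adjusted p = 0.0420; adjusted p = 0.488 with an estimated correlation). The histone call was lost without pBABE replicate 2 (0.257), caMNK replicate 1 (0.104) or caMNK replicate 2 (0.140), with either other filter (0.185 and 0.427), with total-count scaling (0.0788), by fry (0.130) and without genes that share reads (0.111). Its most abundant members Hist1h2ao, Hist1h1c and Hist1h2bc had log2 fold changes of −0.34, 0.085 and −0.020, and Hist1h2ao passed without caMNK replicate 2 (adjusted p = 0.000936). Of 80 ribosomal protein genes, 0 passed in edgeR, also when adjusted over the list alone (median −0.0068, camera adjusted p = 0.793; 0.0182 without pBABE replicate 2), with Rps2 at −0.27 (adjusted p = 0.152; 0.0367 without a filter on low counts), Rplp0 at −0.07 and Rpl13a at 0.08. Of the 120 members of the 4 lists, 13 passed with all libraries, 0 without pBABE replicate 1, 0 without pBABE replicate 2, 5 without caMNK replicate 1 and 23 without caMNK replicate 2.

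Of 11 fibroblast markers tested, Col1a1 fell from 158 ± 8.39 to 93.0 ± 17.2 CPM and, outside the naming rule, Fap rose from 0.840 ± 0.170 to 2.19 ± 0.535 CPM, and 2 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.793). Col3a1 and S100a4, which shares reads with Gm42674, had log2 fold changes of −0.22 and 0.05, and Col3a1 passed without caMNK replicate 2 (adjusted p = 0.00118). Of 7 endothelial markers, Cdh5 (−1.43) and Flt1 (−0.41) fell, and 1 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.597). Eng, which overlaps Fpgs by 61 bp, measured 124 ± 2.11 and 130 ± 2.53 CPM. Of 5 myeloid markers, 0 passed and 1 rose when adjusted over the list alone (camera adjusted p = 0.0898; 0.0298 without pBABE replicate 2 and 0.0483 without caMNK replicate 2). Csf1r, which shares reads with Hmgxb3, measured 12.0 ± 0.856 and 12.3 ± 1.53 CPM, Cd14 3.11 ± 0.281 and 3.30 ± 0.533 CPM and Cd68 2.04 ± 0.233 and 3.28 ± 0.947 CPM (adjusted p = 0.144; 0.00415 without caMNK replicate 2 and 0.0180 without a filter on low counts). Of 3 keratinocyte markers tested, Itga6 fell (−0.48, adjusted p = 0.0246), and 1 rose and 1 fell when adjusted over the list alone. Krt10 had a log2 fold change of 0.40 (adjusted p = 0.113). That of Krt15 was 0.67 (0.612), on 11 and 2 counts in pBABE and 11, 5 and 15 in caMNK. The lymphocyte marker tested, Cd79a, measured 0.211 ± 0.0954 and 0.282 ± 0.126 CPM. Of the 27 markers tested, 5 passed with all libraries, 1 without pBABE replicate 1, 0 without pBABE replicate 2, 0 without caMNK replicate 1 and 12 without caMNK replicate 2.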

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

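Leaving out genes that share reads was chosen only after the data were seen; the other alternatives were fixed before. Over all alternatives the log2 fold change of Mknk1 lay between 3.28 and 3.42, past the threshold in each. DESeq2 size factors, TMM without the 50 most abundant genes, total-count scaling, DESeq2 and limma-voom kept each count of calls within 1.5 times. Without a filter, 1591 genes rose, 1330 fell and 639 rose by 2-fold, over 27978 genes tested. In that fit Mknk1 had a like log2 fold change (3.35) but an edgeR adjusted p of 5.54e-144, against 4.81e-06 in the main fit. The p-values of these fits are thus not on the same scale, and passes without a filter are no further support. The cause of the difference was not tested. With the stricter filter, which removes low-abundance genes, 160 rose and 53 fell by 2-fold. Without genes that share reads, 402 rose and 282 fell (199 and 54 by 2-fold), over 9881 genes, and 8 lists were called against 14. With an estimated correlation camera called 0 lists (smallest adjusted p 0.454, with 1 list at an unadjusted p under 0.05), and fry called 12. That form of camera had little power on 5 libraries, even where the estimated correlation was below the preset. For the nuclear non-coding RNAs it was −0.0685, and the unadjusted camera p went from 0.000486 to 0.0353. The loss of the calls thus does not decide whether correlation of members made them. Leaving out each library in turn gave 11 to 2325 rises, 12 to 2617 falls, 11 to 677 rises and 11 to 179 falls by 2-fold, and 9 to 13 lists. Fewer libraries are part of the cause for the low ends, since pBABE then has a lone library that is assumed to vary like the caMNK libraries. The high ends came without caMNK replicate 2, the library farthest from its group. All 1352 calls kept their direction wherever they were tested. The separation of every called gene all but fixed this in advance, since the alternatives use the same libraries or fewer. It is no further support for the calls. At 27827199 counts or more per library, depth limits genes with few counts, such as Cdkn2b, named outside the rule, with 3 and 6 in pBABE.

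With a replicate block, 1477 genes rose, 1231 fell, 555 rose by 2-fold, and 7 lists were called. Replicate number 3 occurs in caMNK alone, so its block term fits that library exactly. The contrast then rests on replicates 1 and 2 of each group. Mknk1 had an edgeR adjusted p of 2.86e-145 with the block, against 4.81e-06 in the main fit. Passes with the block are therefore no further support. Calls were lost for the invasive (camera adjusted p = 0.0564), ER stress (0.0598), ERK (0.0869), YAP (0.0879), cytokine (0.0952), immediate early (0.155) and G2 and M phase lists (0.179). Eif4ebp2, Eif4ebp3, Hps4, Slc24a5, H2-Q7, Nlrc5, Btg2, Ctsz and Rps2 passed with the block, with edgeR adjusted p-values from 1.39e-05 (H2-Q7) to 0.0422 (Nlrc5). The numbers share no stated culture or day, and deviations of same-numbered libraries correlated at −0.0549 (pair 1) and −0.0252 (pair 2), so the numbers give no sign of pairing.

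The MNK list, down in camera, turned up with the stricter filter (mean log2 fold change 0.15) and with fry (mean 0.13, adjusted p = 0.0141). Its mean is above 0 because it holds the introduced Mknk1: over the other 18 members it was −0.052, and −0.032 with the stricter filter. For the other direction changes the cause was not tested. Mean log2 fold changes of the other lists whose direction turned were −0.0327 (block) and −0.0254 (no shared reads) for antigen presentation, 0.050 (total-count) and 0.0153 (stricter filter) for S phase, 0.0150 (stricter filter) for lysosome, 0.0496 (total-count), 0.0152 (stricter filter) and 0.0181 (no shared reads) for ribosomal proteins, and −0.0349 (stricter filter) for fibroblast markers. Without a library these lists lay between 0.11 and 0.14 (MNK), −0.0947 and 0.14 (antigen presentation), −0.0286 and 0.0150 (S phase), −0.0715 and 0.0675 (lysosome), −0.0891 and 0.0688 (ribosomal) and 0.00846 and 0.19 (fibroblast). Among genes, Hist1h2bc was at 0.0334 (total-count) and 0.0504 (block), Rpl13a at −0.0508 (block) and Csf1r at −0.0494 (block). Without a library the ranges were −0.15 to 0.00872 for Rplp0, −0.0470 to 0.19 for Rpl13a, −0.0144 to 0.18 for Hist1h1c, −0.0787 to 0.0539 for Hist1h2bc, −0.0450 to 0.14 for S100a4, −0.0469 to 0.14 for Csf1r and −0.0182 to 0.20 for Cd14.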

Other observations

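The tests of overlapping genes, of the exonic share and of mitochondrial tRNAs, and the weighting of other genes to the abundance of snoRNAs, were chosen only after the result was seen, and the genes of the next paragraph and Snora73b, named outside the rule, after their values were seen.

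Angptl4, which encodes an inhibitor of lipoprotein lipase, rose from 1.30 ± 0.444 to 10.5 ± 3.5 CPM, 8.20-fold (SD, n = 2 and 3; edgeR adjusted p = 0.00524). Pdk4, a pyruvate dehydrogenase kinase gene, rose from 0.867 ± 0.131 to 4.08 ± 1.07 CPM (adjusted p = 0.00653), while Pdk1 fell. Txnip, which restrains glucose uptake and shares reads with Gm15441, rose from 1.52 ± 0.0828 to 6.27 ± 2.87 CPM (adjusted p = 0.0176). The lipid genes Lpl, Fads2 and Scd2 fell, with log2 fold changes of −1.53, −0.91 and −0.68 (adjusted p of 0.0110, 0.00285 and 0.0153). Cdkn2a, which encodes the cell cycle inhibitors p16 and p19Arf (chromosome 4, 89274471 to 89294653), had 95 and 46 counts in pBABE and 276, 344 and 442 in caMNK, a 5.05-fold rise (adjusted p = 0.00524). Its neighbour Cdkn2b had 3 and 6 counts in pBABE and 16, 30 and 19 in caMNK (adjusted p = 0.0265). Mmp12, a macrophage elastase gene close to Mmp3, Mmp1a and Mmp10 on chromosome 9, rose from 0.634 ± 0.0198 to 1.43 ± 0.212 CPM and shares reads with Mmp1b (adjusted p = 0.0299).

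Small nucleolar RNAs guide the modification of ribosomal RNA. The counts here are of reads at snoRNA entries, 149 of which overlap a tested host gene. The recovery of such short RNAs by the preparation was not tested, so these counts do not give the amounts of mature snoRNA. Of 164 snoRNA entries tested, 38 rose and 0 fell, and 33 rose by at least 2-fold, which is 20.1% against 1.96% of the other genes (odds ratio 12.6, two-sided Fisher's exact test across genes, p = 5.98e-23; genes are not independent replicates). Rises of 2-fold were more frequent among low-abundance genes, and weighting the other genes to the abundance of the snoRNA entries raised their share to 4.70%. The median log2 fold change was 0.74 for the snoRNA entries and 0.16 for the other genes so weighted. The count of rises among snoRNA entries was 0 without pBABE replicate 1, 1 without pBABE replicate 2, 12 without caMNK replicate 1, 67 without caMNK replicate 2 and 45 without caMNK replicate 3. Snora73b rose from 1.29 ± 0.0602 to 4.89 ± 0.849 CPM and lies inside Rcc1, whose reads its entry shares in part.

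Low-abundance genes were shifted upward in caMNK: the median log2 fold change was 0.43 in genes with a mean log2 CPM under −1 and −0.08 above 7. The filter, which passes genes seen in few libraries of the larger group, was set against genes chosen by the mean of the group means; their median log2 ratio was still 0.208 (95% interval 0.181 to 0.235), which argues against the filter as the whole cause. Background spread evenly along the genome, as measured in isolated receptor genes, would give a share of 0.109 (0.0397 to 0.213) of the extra CPM, less than the explanation needs. Reads at these receptor genes did rise, from 0.383 CPM per Mb in pBABE to 0.670 in caMNK (group means). More background in caMNK therefore stays open as a part of the shift. Overlap with other genes as the whole cause is argued against by isolated protein-coding genes with a mean log2 CPM under 0. Their median was 0.461 (0.415 to 0.549, 642 genes). These genes had passed the filter, and the genes chosen without it were not limited to isolated ones. A joint effect of filter and overlap was therefore not tested. An effect of the kinase, another difference between the cell lines and a difference in RNA preparation that favours rare transcripts all stay open, untested.

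Among nuclear non-coding RNAs 6 of 11 rose and 1 fell, among mitochondrial mRNAs 6 of 10 rose, and among snoRNA entries 38 of 164 rose. The non-coding and mitochondrial lists each have a camera adjusted p of 0.454 with an estimated correlation. Some of the non-coding RNAs that rose, such as Gas5, are snoRNA host genes. Their gene-body counts take in reads of the snoRNAs inside them, so the non-coding and snoRNA rises are in part the same evidence. A larger share of unspliced nuclear RNA would raise genes that are mostly intron, yet the genes with the smallest exonic share lay below those with the largest by −0.0774 in median log2 fold change (−0.103 to −0.0616). More mitochondrial RNA of every class would raise the 20 mitochondrial tRNA genes. Their median was −0.0401 (−0.421 to 0.189), and 1 rose and 0 fell. The recovery of such short RNAs by the preparation was not tested, so these entries do not decide the question. The snoRNA entries exceeded their hosts by a median of 0.586 (0.460 to 0.717, 149 entries). A change like that of the whole host gene thus does not account for theirs. Host reads at the entries themselves were not measured, and hosts were not matched to entries by abundance. The excess therefore does not exclude local reads of the hosts. An effect of the kinase on these RNAs, another difference between the cell lines and a preparation difference between the groups all stay open, untested. The labels give no date or batch of preparation.

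Of the 95 members of the ATF4, hypoxia and cholesterol lists, 52 fell and 1 rose, with a median of −0.39; each list has an adjusted p of 0.454 with an estimated correlation. After trends with GC content, gene span and abundance over all genes were removed, the median of the 93 members with these values was −0.355 (−0.408 to −0.308), which argues against such a trend as the whole cause. In the 5 fits without a library, the medians lay between −0.402 and −0.393. The size of the fall thus does not rest on 1 library, although the count of calls does. Its direction was all but fixed in advance, since the 52 called falls are separated in every library, and is no further support. An effect of the kinase, another difference between the cell lines, and a difference in culture density or medium age all stay open, untested. The labels do not give density or medium age. The preparation difference left open for the nuclear and mitochondrial RNAs of the same libraries stays open here too.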
